A study of Mus musculus with 4 samples.

How the data were processed

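The series holds 4 libraries from cortical nuclei of mice aged 8 weeks, isolated through a nuclear membrane tag expressed in CamkIIa-positive cells: 2 MeCP2 ChIP libraries and 2 input libraries, numbered 1 and 2 in each group. The labels do not say whether the numbers stand for separate animals or preparations, so p-values measure only the spread between these libraries, which may be technical. With 2 libraries per group an exact permutation test could not go below p = 0.333.

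The deposited table gives whole-number read counts for 25205 gene intervals with start and stop, 1 column per library, not normalized. Reads were handled with Bowtie2 2.2.4, SAMtools and bedtools on the genome build mm10, per the submitters' processing notes. Read filters, duplicate handling, the counting rule and strand are not given in the sources used here. No row lacks a gene name, 47 symbols occur more than once, and 26 rows carry spreadsheet dates in place of symbols (tested but not named). The authors also deposited a log2 ratio per replicate, headed as a fold change, computed from unscaled counts and missing at 38 intervals in replicate 1 and 149 in replicate 2 where a count is 0. Recomputed from the counts, the ratio of replicate 1 is ChIP over input and that of replicate 2 is input over ChIP as the count columns are headed. Either the headers of the replicate 2 counts or the sign of that ratio are turned, and no other label tells which. Library names below and in the report follow the headers. No genome sequence was used here, so GC content was not examined.

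Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, estimateDisp, glmQLFit and glmQLFTest), limma 3.58.1 and DESeq2 1.42.0, and plots were drawn with matplotlib 3.10.9. Genes with at least 10 counts in at least 2 libraries (24009) were tested at a Benjamini-Hochberg adjusted p of 0.05, with the group as the single term. A log2 ratio is relative to the typical gene, since TMM sets the bulk of genes to no difference, and it is not an absolute occupancy. Its standard error (SE) is the log2 ratio divided by the square root of the quasi-likelihood F. The totals of 10444644 to 13883207 counts per library gave a median of 111 to 168 counts per gene, and counting intervals cover counting error only. The main comparison, with columns as headed, was fixed before the data were examined. The comparison with the replicate 2 libraries exchanged was added after the counts had been seen.

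Gene lists were also fixed before the data were examined: excitatory neuron, inhibitory neuron, astrocyte, oligodendrocyte lineage, microglial and vascular markers, genes described as MeCP2-regulated, imprinted, germline, developmental transcription factor, immediate early, long synaptic, glutamate and GABA receptor, potassium channel, ribosomal protein, proteasome, respiratory chain, olfactory receptor, vomeronasal receptor, keratin, clustered protocadherin, Zfp zinc finger, histone and Y-linked genes. The 24 lists were tested with camera (preset correlation 0.01, adjusted over the lists), and beside it with camera's estimated correlation and with fry. Camera compares a list with the other genes, and fry asks whether its genes move, on balance, one way.

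Named genes followed a fixed rule. Among called genes with a mean of at least 50 counts, both ChIP libraries on the same side of both inputs and a symbol of a named gene, the 12 with the largest positive and the 12 with the largest negative log2 ratio were taken, at most 2 per symbol family, and where fewer passed, those of smallest p filled up to 12. Mecp2 and Camk2a were added, from each list past the threshold its 2 called members with the largest and its 2 with the smallest ratio, and from other lists up to 2 of smallest p. For lists as headed these members are not printed, since no gene was called. Members of lists were not held to a mean of 50 counts, and some of those printed had fewer.

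Length is that of the interval. X-linked and autosomal genes were compared by medians. The code was tested on simulated data with 100 of the 24009 genes changed by a log2 of 0.5, 100 by a log2 of 1 and a list of 60 by a log2 of 0.3. For the comparison as headed it recovered 1 and 34 of the first and second set (36 calls, 1 on an unchanged gene), and for the exchanged comparison 35 and 91 (140 calls, 3 on genes of the list and 11 on unchanged genes). Alternatives were DESeq2 size factors, library totals, no count filter, a mean of at least 100 counts, DESeq2's Wald test, leaving out each library, the replicate number as a block, 1 interval per symbol, a minimum fold of 1.2, and, chosen after seeing the data, exchanged libraries, a crossed block and intervals that overlap no other.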

Results

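MeCP2, a protein that binds methylated DNA, was immunoprecipitated from crosslinked chromatin of mouse cortical nuclei, and reads were counted over gene intervals beside those of input chromatin. The nuclei came from C57BL/6 mice aged 8 weeks that carried a tagged nuclear membrane protein in cells expressing CamkIIa, a marker of excitatory neurons, and were isolated through that tag. The table held 2 MeCP2 ChIP libraries and 2 input libraries, numbered 1 and 2, over 25205 intervals. Reads over the intervals totalled 13724561 in the library headed ChIP 1, 13883207 in input 1, 10444644 in ChIP 2 and 10692038 in input 2. Of the intervals, 24009 had at least 10 reads in at least 2 libraries and were tested, and 7437 of these (31%) overlapped another interval. The comparison asked which genes carried more or fewer MeCP2 ChIP reads than input reads, relative to the typical gene.

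With the columns taken as headed, no gene stood apart between ChIP and input by more than the spread between replicates. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower in ChIP (2 libraries per group, smallest adjusted p = 1), and 16 genes had an unadjusted p below 0.05 where 1200 would be expected by chance. DESeq2 also called 0 genes, with 0 at an unadjusted p below 0.05. Counts so far below chance mean that the spread within groups was large against the difference between them. The 0 calls therefore do not show that ChIP and input were alike. None of those 16 met the fixed rule for naming genes, which asks for a mean of at least 50 reads, both ChIP libraries on the same side of both inputs and a symbol of a named gene, with at most 2 genes per symbol family. The genes of smallest p that met it, none of which passed the edgeR test, were Trim40 (log2 ratio 0.63 ± 0.31 SE), Clec4e (0.60 ± 0.33), Oas1a (0.54 ± 0.29), Cylc1 (0.54 ± 0.31), Vmn1r51 (0.60 ± 0.35), Prss58 (0.55 ± 0.33), Rapsn (0.52 ± 0.31), Mex3b (0.59 ± 0.36), Tymp (0.55 ± 0.34), Xbp1 (0.55 ± 0.34), Dpm3 (0.49 ± 0.31) and Pabpn1 (0.51 ± 0.32) on the positive side. On the negative side the genes of smallest p that met the rule were Calm1 (−0.52 ± 0.30), Zfp36l1 (−0.59 ± 0.34), Sox4 (−0.57 ± 0.33), Krt86 (−0.50 ± 0.30), Zbtb18 (−0.47 ± 0.30), Ptf1aos (−0.54 ± 0.34), Hey1 (−0.52 ± 0.34), Zfp663 (−0.37 ± 0.24), Srprb (−0.39 ± 0.26), Far2os1 (−0.45 ± 0.30), Apol7c (−0.47 ± 0.32) and Hypk (−0.51 ± 0.34).

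As headed, no member of the 24 gene lists fixed beforehand was called, whether adjusted over all genes or adjusted over the list alone. Camera with a preset correlation still set 7 lists apart from the other genes. Higher were the vomeronasal receptors (median log2 ratio 0.14, 192 tested, adjusted p = 4.71e-07), the olfactory receptors (0.10, 912 tested, adjusted p = 3.63e-06) and Y-linked genes (0.10, 8 tested, adjusted p = 0.0321). Lower were excitatory neuron markers (−0.11, 30 tested, adjusted p = 3.63e-06), immediate early genes (−0.07, 34 tested, adjusted p = 0.00119), very long synaptic genes (−0.06, 60 tested, adjusted p = 0.00119) and potassium channels (−0.03, 83 tested, adjusted p = 0.00477). None of the 7 held with an estimated correlation (adjusted p = 0.941 with an estimated correlation for each) or in fry (adjusted p = 1). Without the library headed input 2, 6 of them changed sign, all but the excitatory neuron markers. The mean, median and camera direction of 2 other lists differed in sign: clustered protocadherins (median −0.05, mean 0.02, up) and ribosomal proteins (median 0.01, mean −0.02, down).

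The replicates' ratios ran against each other gene by gene. As headed, differences between ChIP and input in the single replicates thus added to the spread within groups. edgeR's common dispersion, which measures that spread, was 0.0339 as headed and 0.00631 with the replicate 2 libraries exchanged (below). Hox and other developmental transcription factors had a median log2 ChIP over input ratio of −0.81 in replicate 1 and 0.75 in replicate 2 as headed, and clustered protocadherins −0.47 and 0.59. Astrocyte markers, in the other direction, had medians of 0.25 and −0.18. Across the 24009 genes Spearman's rho between the 2 ratios was −0.663 (Pearson's r = −0.606, and −0.816 over the 14641 genes with a mean of at least 100 reads). These correlations are across genes, which are not independent replicates. The authors' deposited log2 ratio of replicate 1 equalled ChIP over input at all 25167 intervals where it was finite, and that of replicate 2 equalled input over ChIP, as the columns are headed, at all 25056, to a tolerance of 1e-05. At 542 of the latter intervals the counts were tied, so that both readings matched. The 2 deposited ratios correlated at Pearson's r = 0.815 over genes with a mean of at least 100 reads. Of the library pairs, the one headed input 1 and ChIP 2 had the highest Pearson correlation of depth-scaled log2 counts (0.991), followed by ChIP 1 and input 2 (0.985) and, close to it, ChIP 1 and input 1 (0.984). ChIP 1 and ChIP 2 stood at 0.978, ChIP 2 and input 2 at 0.977 and the inputs at 0.975.

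**Figure D1:**
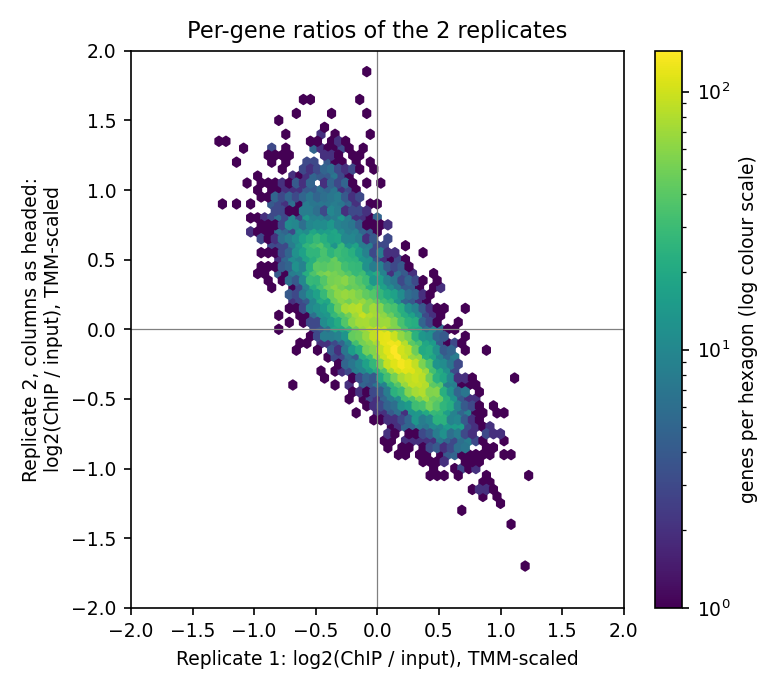
Log2 ChIP over input of replicate 1 (x axis) against that of replicate 2 with columns as headed (y axis), TMM-scaled, for the 14641 genes with a mean of at least 100 reads; colour gives genes per hexagon on a log scale. The cloud slopes downwards (Pearson's r = −0.816).

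The comparison was therefore also made with the libraries of replicate 2 exchanged, which is the direction of the authors' deposited ratio, so that the libraries headed ChIP 1 and input 2 form the ChIP side and those headed input 1 and ChIP 2 the input side. This assignment was chosen after the counts were seen and partly from them. The p-values that follow are conditional on it, and the counts do not by themselves settle which header is wrong. Everything below, unless stated otherwise, is given for the exchanged libraries.

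After the exchange, Lhx1, a LIM homeobox factor, had the lowest ratio of the genes named by the fixed rule of size, 2.67-fold lower on the ChIP side (log2 −1.41 ± 0.22 SE, n = 2 libraries per side), and the homeobox genes Hmx2 (−1.39 ± 0.20), Hoxb6 (−1.38 ± 0.27), Six1 (−1.35 ± 0.17), Pitx2 (−1.35 ± 0.16), Irx4 (−1.30 ± 0.25) and Pdx1 (−1.28 ± 0.30) were lower by similar amounts. Highest by that rule was Insm2, a zinc finger factor of neuroendocrine cells, at 2.71-fold (1.44 ± 0.23), followed by Mab21l1 (1.32 ± 0.27), Skida1 (1.26 ± 0.17), Car3, a carbonic anhydrase (1.16 ± 0.17), and Id4, an inhibitor of helix-loop-helix factors (1.14 ± 0.24). In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2374 genes higher and 2291 lower, 19.4% of those tested.

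The remaining genes named by the fixed rule were, on the higher side, Abra (1.12 ± 0.19), Fam46a (1.10 ± 0.22), Zadh2 (1.09 ± 0.15), Clec14a (1.05 ± 0.20), Tex9 (1.04 ± 0.11), the growth factor gene Fgf5 (1.03 ± 0.13) and Olfr1260 (1.03 ± 0.21), an olfactory receptor of a family in which reads can be shared between paralogs. On the lower side they were Irx3os (−1.39 ± 0.23), the corepressor gene Skor1 (−1.36 ± 0.22), the splicing factor gene Puf60 (−1.34 ± 0.20), Vax2os (−1.30 ± 0.16) and Osr2 (−1.23 ± 0.21). Adjusted p-values of these 24 genes in edgeR's quasi-likelihood test ran from 0.00485 for Tex9 to 0.0175 for Pdx1. In the build mm10, per the submitters' processing notes, Insm2 spans chromosome 12, 55598917 to 55602018, and Lhx1 chromosome 11, 84518284 to 84525535. Six1 spans chromosome 12, 73040015 to 73053887, Pitx2 chromosome 3, 129199878 to 129219591, and Tex9 chromosome 9, 72450394 to 72492212. The intervals of Mab21l1, Id4, Tex9, Irx3os, Hmx2, Hoxb6, Pitx2, Vax2os and Pdx1 overlap another interval, and, with no strand given, their reads cannot be told from those of the neighbour. The same holds for list members named below, besides those marked there: Nkx6-2, Wwox, Tdrd9, Psma5, Psma3, Cux1, Maf, Nkx2-1 and Cnp. It also holds for Ermn, P2ry12, Reln, Ube3a, Ddc, Snrpn, Grin1 and Kcnip1. Lhx1 rested on 31 reads in each ChIP-side library against 97 and 80 on the input side, and Tex9 on 1019 and 921 against 598 and 419.

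**Figure D2:**
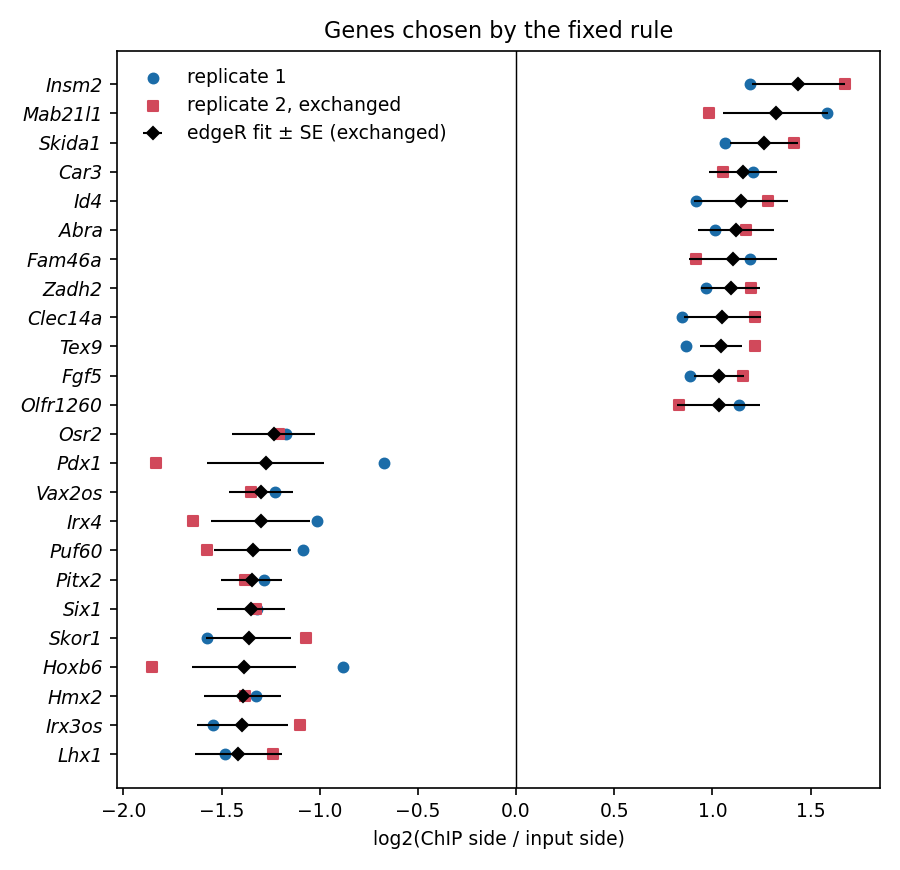
Log2 ratio of ChIP side to input side for the 24 genes chosen by the fixed rule, replicate 2 exchanged. Circles and squares give the replicates against their own input (TMM-scaled), and diamonds the edgeR fit with its standard error, from −1.41 for Lhx1 to 1.44 for Insm2.

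Most called differences were small: the median log2 ratio was 0.45 among genes called higher and −0.55 among those called lower, and 49 and 182 genes exceeded a 2-fold difference. Intervals that overlap no other made up 1619 of the genes called higher and 1445 of those called lower. Scaling by library totals alone, which moved the median of all genes by −0.10 on the log2 scale, turned the split from 50.9% higher to 26.9% higher (1330 higher and 3619 lower), and with DESeq2 it was 64.7% (1483 higher and 809 lower). Leaving out 1 library moved these counts by side: fewer genes were called without either input-side library, and more without either ChIP-side library. Such a fit takes its spread from the side that keeps 2 libraries. The input-side pair correlated at 0.991 and the ChIP-side pair at 0.985, and the main fit pools their spreads. Each of the 24 named genes kept its sign in every fit it entered, which the rule made near certain. It asked for both ChIP-side libraries on the same side of both inputs. Without an input-side library, some of the 24 and many of the list members named below lost their call.

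Of 121 tested Hox and other developmental transcription factors, 57 were lower, 4 higher and 60 not called (68 and 5 adjusted over the list alone), with a median log2 ratio of −0.82 and medians of −0.81 and −0.75 in the replicates. Camera gave adjusted p = 5.84e-14, and adjusted p = 0.313 with an estimated correlation. This was the 1 list of 24 past the threshold in fry (adjusted p = 0.0344). Genes with Hoxa, Hoxb and Hoxd symbols each lie on 1 chromosome. Neighbouring genes over 50 kb apart had alike ratios (rho = 0.35 between replicates), so the 121 genes are not separate measurements. Hoxc12 had 4 reads in the 2 ChIP-side libraries together and 43 on the input side, a ratio of 10.8-fold lower before scaling (95% counting interval 3.92 to 41.4). Nkx2-5, a heart regulator, was at −2.46 ± 0.41, on 6 and 5 ChIP-side reads against 38 and 28. The called members furthest in the other direction were Nkx6-2 (1.03 ± 0.26) and Alx1 (0.48 ± 0.13).

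Clustered protocadherins, cell surface proteins encoded in a tandem array on chromosome 18, were lower at 36 of 58 intervals and higher at 0, with 22 not called (47 lower adjusted over the list alone) and a median of −0.53. Among the called members Pcdhb20 (−1.46 ± 0.38) and Pcdhb14 (−0.98 ± 0.26) lay at one end and Pcdhgb8 (−0.28 ± 0.09) and Pcdhga11 (−0.29 ± 0.09) at the other. Pcdhb20 had 24 and 7 ChIP-side reads against 45 and 45. The 58 intervals overlap into 23 distinct loci and share reads, so their counts are not separate measurements. Camera gave adjusted p = 1.34e-19, and adjusted p = 0.379 with an estimated correlation. Zinc finger genes with Zfp symbols were lower at 90, higher at 11 and not called at 220 of 321 (130 lower and 16 higher adjusted over the list alone), with a median of −0.38. Zfp873 (−1.11 ± 0.20) and Zfp606 (−1.03 ± 0.17) were lowest among the called members, and Zfp395 (0.84 ± 0.10) and Zfp521 (0.76 ± 0.11) highest. For this list camera gave adjusted p = 2.06e-11, and adjusted p = 0.379 with an estimated correlation.

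Nuclear-encoded respiratory chain subunits were lower at 25, higher at 2 and not called at 52 of 79 genes (30 lower and 2 higher adjusted over the list alone; median −0.46). Ndufa2 (−1.24 ± 0.37, in an interval that overlaps another) and Ndufa11 (−1.06 ± 0.22) were lower, and Ndufa5 (0.46 ± 0.14) and Cox7b2 (0.33 ± 0.09) higher. Among 39 proteasome subunits 11 were lower, 0 higher and 28 not called (14 lower adjusted over the list alone; median −0.42), with Psma1 at −0.89 ± 0.17, Psmd2 at −0.87 ± 0.17, Psma5 at −0.45 ± 0.11 and Psma3 at −0.42 ± 0.11. Among 83 ribosomal protein genes 11 were lower, 0 higher and 72 not called (3 lower adjusted over the list alone; median −0.38), including Rplp2 (−1.33 ± 0.24), Rpl19 (−1.18 ± 0.24), Rpl4 (−0.79 ± 0.20) and Rpl21 (−0.70 ± 0.22). Ribosomal protein genes have many processed pseudogenes, so reads could be placed at more than 1 copy. Camera's adjusted p-values were 1.46e-07, 1.83e-06 and 0.000157 for the respiratory chain, proteasome and ribosomal lists. The first and second of these gave adjusted p = 0.379 with an estimated correlation, and the ribosomal list adjusted p = 0.66 with an estimated correlation.

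Astrocyte markers were higher at 7, lower at 0 and not called at 17 of 24 genes (8 higher adjusted over the list alone; median 0.22), among them Gjb6, a gap junction protein (0.86 ± 0.18), Cldn10 (0.65 ± 0.08), Slc14a1 (0.34 ± 0.09) and Slc4a4 (0.31 ± 0.09). Germline genes were higher at 5, lower at 0 and not called at 28 of 33 (5 higher adjusted over the list alone; median 0.18), with the germ cell RNA-binding protein gene Dazl at 0.78 ± 0.17, Tdrd1 at 0.52 ± 0.10, Tdrd9 at 0.32 ± 0.09 and Tex15 at 0.31 ± 0.09. Genes of the long synaptic list were higher at 13, lower at 0 and not called at 47 of 60 (15 higher adjusted over the list alone; median 0.15), including Wwox (0.70 ± 0.09), Epha7, an ephrin receptor (0.51 ± 0.09), Pcdh15 (0.33 ± 0.10) and the glutamate receptor gene Grm8 (0.31 ± 0.10). Their median length was 1030 kb. The top length decile of all tested genes had 744 of 2401 higher, 170 lower and a median of 0.18. The list's median thus did not exceed that of long genes in general. Camera, which compares with all other genes, gave adjusted p = 0.0011, 0.00206 and 0.000157 for the astrocyte, germline and long synaptic lists. With an estimated correlation, adjusted p = 0.379 for astrocyte and germline genes and adjusted p = 0.66 for the long synaptic genes, each with an estimated correlation. DNA is present in nuclei whether or not a gene is expressed, so a marker list describes the chromatin of those genes in the isolated nuclei and not a share of cells.

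Calls for 3 further lists rested on single libraries. Replication-dependent histone genes had a median of 0.32 over 55 genes, with 1 called higher, 0 lower and 54 not called (0 adjusted over the list alone). The called gene was Hist1h2bl (1.62 ± 0.51), which has near-identical copies. It had 18 and 17 ChIP-side reads against 5 and 7. Camera gave adjusted p = 0.0332 for the histone list, 0.11 without input 1 (median 0.28) and 0.483 without the library headed input 2 (median 0.13). Y-linked genes were lower at 3 of 8 (4 adjusted over the list alone), higher at 0 and not called at 5, with a median of −0.51, and the 3 were Kdm5d (−0.74 ± 0.20), Eif2s3y (−0.68 ± 0.21) and Uty (−0.50 ± 0.11). Camera gave adjusted p = 0.00338 for them and 0.116 without the library headed input 2 (median −0.19). Vomeronasal and trace amine receptors, separate families that each hold close paralogs, had a median of −0.32 over 192 genes, with Vmn1r21 higher (0.72 ± 0.17), Vmn1r50 (−0.71 ± 0.22) and Vmn2r114 (−0.67 ± 0.19) lower and 189 not called (0 adjusted over the list alone). Camera gave adjusted p = 0.0451 for the receptors, 0.626 without input 1 (median −0.07) and 0.435 with library totals (median −0.42), and their median was 0.03 without the library headed input 2. With an estimated correlation none of these lists passed: adjusted p = 0.663 for histones, 0.66 for Y-linked genes and 0.85 for the receptors, each with an estimated correlation. The other 9 of the 12 lists past camera's threshold passed in every fit that left out 1 library.

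**Figure D3:**
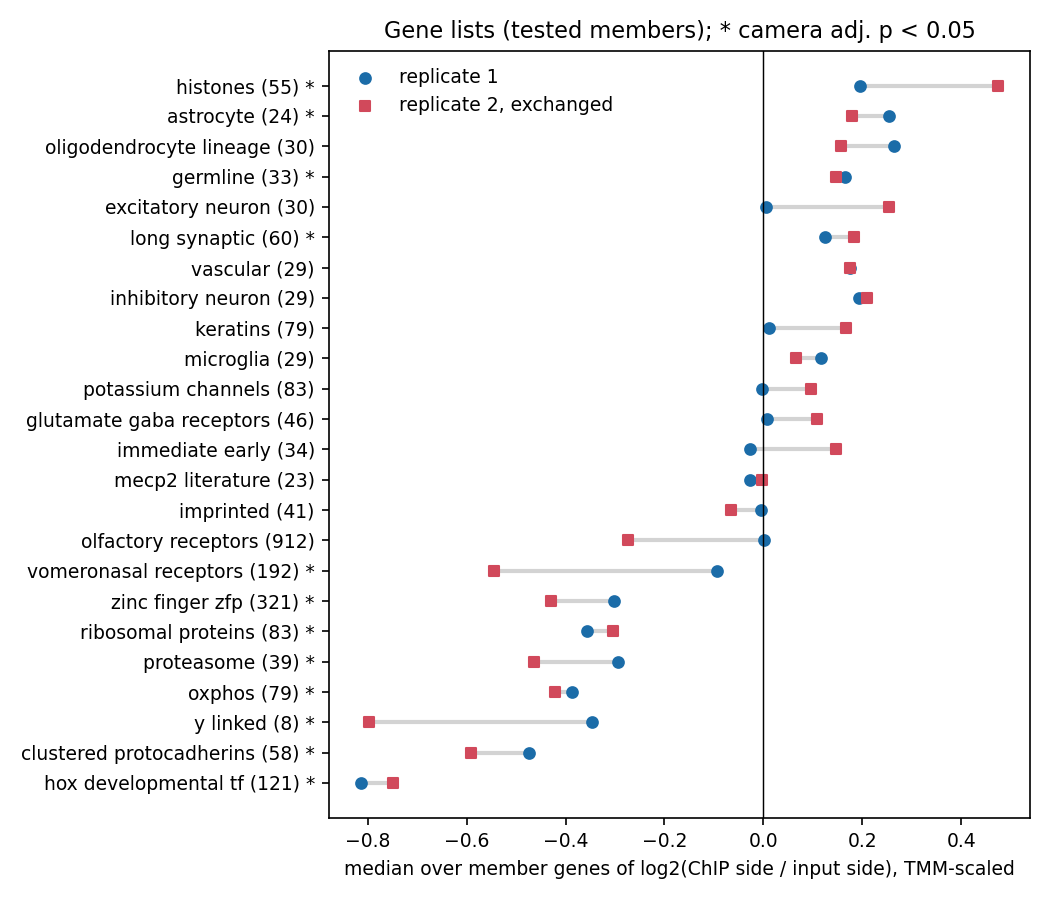
Median log2 ratio over the tested members of each of the 24 gene lists, for replicate 1 (circles) and replicate 2 exchanged (squares), TMM-scaled; asterisks mark lists with a camera adjusted p below 0.05. Hox and other developmental factors lie lowest in replicate 1 (−0.81), and with library totals alone the medians of microglial, immediate early, receptor, potassium channel and keratin lists turn negative.

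The remaining 12 lists did not pass camera. Excitatory neuron markers had 5 higher, 1 lower and 24 not called (the same numbers adjusted over the list alone; median 0.16, adjusted p = 0.139), with Cux1 at 0.54 ± 0.10 and the synaptic scaffold gene Baiap2 at −0.63 ± 0.12. Inhibitory neuron markers had 5 higher and 4 lower of 29 (10 and 6 adjusted over the list alone, adjusted p = 0.153). Their median of 0.11 and mean of −0.04 differed in sign. Their called members included Maf (0.99 ± 0.11) and Kit (0.50 ± 0.08), which were higher, and Nkx2-1 (−1.47 ± 0.31) and Dlx5 (−1.27 ± 0.34), which were lower. Oligodendrocyte lineage genes had 8 higher and 2 lower of 30 (9 and 3 adjusted over the list alone; median 0.20, adjusted p = 0.0603). The 2 lower were Olig2, a lineage-defining factor, at −1.51 ± 0.33 and the myelin gene Cnp at −0.63 ± 0.13. Olig2 rested on 12 and 13 ChIP-side reads against 45 and 32. Those higher included Nkx6-2 (1.03 ± 0.26) and Ermn (0.78 ± 0.17). Microglial markers had 3 higher and 0 lower of 29 (3 adjusted over the list alone; median 0.09, but −0.0057 with library totals, adjusted p = 0.135), including P2ry12 (0.41 ± 0.09) and Ptprc (0.40 ± 0.09). Vascular markers had 4 higher and 1 lower of 29 (4 and 1 adjusted over the list alone; median 0.15, adjusted p = 0.0635), with Ptprb at 0.47 ± 0.09 and the endothelial factor gene Sox17 at −1.11 ± 0.23. Leaving out 1 library brought several of these past camera's threshold: excitatory markers without ChIP 1 (median 0.27, adjusted p = 0.000943), oligodendrocyte genes without the library headed ChIP 2 (median 0.20, adjusted p = 0.047) or input 2 (0.23, adjusted p = 0.0358), microglial markers without the library headed ChIP 2 (median 0.14, adjusted p = 0.047) and vascular markers without the library headed input 2 (median 0.16, adjusted p = 0.0358). Restricting the test to genes with a mean of at least 100 reads did so for inhibitory neuron markers (median 0.25, camera adjusted p = 0.00538) and vascular markers (median 0.14, adjusted p = 0.026).

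Genes described in earlier mouse work as regulated by MeCP2 had 3 higher and 2 lower of 23 (4 and 2 adjusted over the list alone, adjusted p = 0.755 in camera). Among those higher were the stress-response gene Fkbp5 (0.60 ± 0.11) and Reln (0.40 ± 0.09), and the 2 lower were Dlx5 (−1.27 ± 0.34) and Ube3a (−0.42 ± 0.09). Imprinted genes had 5 higher and 2 lower of 41 (5 and 2 adjusted over the list alone, adjusted p = 0.755). Those higher included Ddc (0.69 ± 0.10) and Sgce (0.54 ± 0.09), and the 2 lower were Ube3a and Snrpn (−0.37 ± 0.10). In both of these lists the median (−0.06 and −0.08) was negative while camera's direction was up. Immediate early genes had 3 higher and 1 lower of 34 (1 and 0 adjusted over the list alone; median 0.04, but −0.06 with library totals, adjusted p = 0.339), with Nr4a2 at 0.57 ± 0.12 and the neurotrophin gene Bdnf at 0.34 ± 0.09. Glutamate and GABA receptor genes had 9 higher and 4 lower of 46 (9 and 4 adjusted over the list alone; median 0.06, but −0.04 with library totals, adjusted p = 0.29). Those lower included Grin1 (−0.75 ± 0.12) and Grik5 (−0.71 ± 0.10), and those higher Grm8 (0.31 ± 0.10). Potassium channels had 10 higher and 2 lower of 83 (10 and 2 adjusted over the list alone; median 0.07, but −0.03 with library totals, adjusted p = 0.143), with Kcnip1 at 0.41 ± 0.09 and Kcnq2 at −0.60 ± 0.09. Olfactory receptors had 6 higher and 7 lower of 912 (0 adjusted over the list alone; median −0.13, adjusted p = 0.29), with Olfr1 at −1.29 ± 0.28. Keratins had 2 higher and 0 lower of 79 (0 adjusted over the list alone; median 0.10, but −0.00024 with library totals, adjusted p = 0.149), namely Krt27 (0.76 ± 0.20) and Krtap9-3 (1.30 ± 0.41). Without ChIP 1, camera's adjusted p fell to 0.037 for immediate early genes (median 0.22), 0.0418 for the glutamate and GABA receptors (0.10), 0.0079 for potassium channels (0.11) and 0.000339 for olfactory receptors (−0.45). For the last it was 0.0193 without the library headed ChIP 2 (median −0.21). Library totals gave keratins a camera adjusted p of 0.041. Krtap9-3 rested on 28 and 19 ChIP-side reads against 9 and 11.

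Mecp2 itself, on the X chromosome at 74026592 to 74135363 in an interval that overlaps another, was lower on the ChIP side (−0.35 ± 0.10, adjusted p = 0.0329 in edgeR's quasi-likelihood test). It missed the threshold without input 1 (adjusted p = 0.0895) and without the library headed ChIP 2 (0.345). Camk2a, the gene whose expression defines the nuclei, on chromosome 18 at 60925618 to 60988152, had −0.35 ± 0.13 and was not called (edgeR adjusted p = 0.0767). Its log2 ratio was −0.16 without ChIP 1 (edgeR adjusted p = 0.272), −0.24 without the library headed ChIP 2 (0.44), −0.47 without input 1 (0.096) and −0.53 without the library headed input 2 (3.05e-05). As headed, the same fits gave 0.11 ± 0.23 for Mecp2 and −0.03 ± 0.24 for Camk2a.

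Longer genes carried a higher ChIP-side ratio, a relation that was asked about because MeCP2 and gene length are a standing question of the field. Spearman's rho of the log2 ratio with interval length across genes was 0.172, with 0.136 in replicate 1 and 0.178 in replicate 2 exchanged. The ratio followed gene density, the number of genes within 1 Mb, more strongly (rho = −0.284 and −0.304). With density held fixed, rho with length fell to 0.0414 and 0.0808. Median log2 ratios ran from −0.15 in the second length decile (2.1 to 4.28 kb) to 0.18 in the top decile (103 to 2960 kb), where 744 genes were higher and 170 lower. In the shortest decile, with intervals up to 2.1 kb, the median was −0.05 and 11 genes were higher and 14 lower. As headed, rho was −0.07 and changed sign between the fits that left out 1 library. Genes are not replicates, so no p is given.

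**Figure D4:**
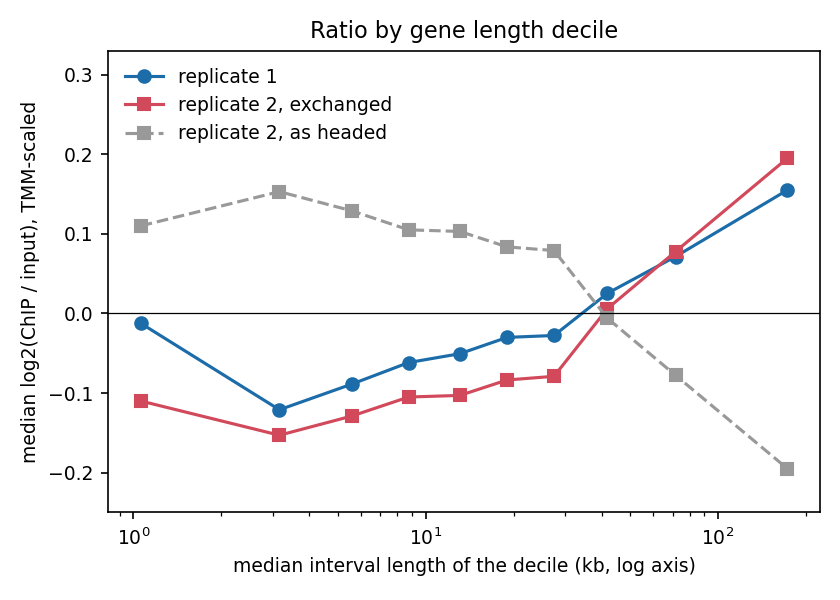
Median log2 ChIP over input (TMM-scaled) per decile of interval length against the decile's median length in kb (log axis), for replicate 1, replicate 2 exchanged and replicate 2 as headed. Replicate 1 and replicate 2 exchanged rise from −0.12 and −0.15 in the second decile to 0.16 and 0.20 in the top one, and replicate 2 as headed mirrors the latter.

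Genes on the X chromosome differed from autosomal genes by less than the replicates differed from each other. The median log2 ratio of the 865 X-linked genes minus that of the 23014 autosomal genes was −0.02 with replicate 2 exchanged and 0.03 as headed. Replicate 1 alone gave 0.01 and replicate 2 exchanged −0.07, so the sign differed between replicates, and the difference ranged from −0.10 to 0.07 when 1 library was left out.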

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

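The exchange of the replicate 2 libraries, the crossed block and the restriction to intervals that overlap no other were chosen after seeing the data. Corrections for GC content and length, alone or with the block, were not run because no GC content was at hand. As headed, 0 genes were called in each of the settings tried, edgeR and DESeq2 alike, with 0 to 804 genes at an unadjusted p below 0.05. Lists past camera's threshold went from 7 to 0 with an estimated correlation and 0 in fry, and ranged from 8 to 15 when 1 library was left out. The length trend then ranged from −0.17 to 0.10 and the X difference from −0.043 to 0.117. The exchange gave 2374 higher and 2291 lower genes, 12 lists, a length trend of 0.172 and an X difference of −0.019. It turned the list medians to 0.16 for excitatory markers, 0.044 for immediate early, 0.15 for long synaptic and 0.068 for potassium channel genes, and to −0.13, −0.32 and −0.51 for olfactory, vomeronasal and Y-linked genes. Leaving out 1 library, the as-headed medians ranged from −0.233 to 0.018 (immediate early), −0.142 to 0.045 (long synaptic), −0.081 to 0.0014 (potassium channels), −0.094 to 0.472 (olfactory), −0.236 to 0.832 (vomeronasal) and −0.377 to 0.84 (Y-linked), each changing sign without the library headed input 2.

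With replicate 2 exchanged, genes called higher and lower numbered 1330 and 3619 with library totals, 1483 and 809 with DESeq2, 258 and 253 against a fold of 1.2, and 1320 and 1246 among intervals that overlap no other (fewer genes tested). Leaving out 1 library gave 58 to 3742 higher and 81 to 3513 lower, 10 to 17 lists, a length trend of 0.139 to 0.192 and an X difference of −0.099 to 0.066. The lone library of a side was then assumed to vary like the others. Lists went from 12 to 0 with an estimated correlation and 1 in fry, and the vomeronasal median ranged from −0.871 to 0.035 when 1 library was left out, above 0 without the library headed input 2. In the other settings of the exchanged fit that use all libraries, camera's call was unchanged in 159 tests of lists, gained in 4 and lost in 2. Gained were keratins with library totals (adjusted p = 0.041), inhibitory and vascular markers with a mean of at least 100 counts (0.00538 and 0.026), and lost were vomeronasal receptors with library totals (0.435). The replicate block, given last, made the other change of each kind. With library totals the medians of microglial (−0.0057), immediate early (−0.06), glutamate and GABA receptor (−0.04), potassium channel (−0.03) and keratin genes (−0.00024) turned negative. The cause of these shifts was not tested. DESeq2 gave an adjusted p for 7 of the 24 genes named by size, and all 7 passed. In the shortest length decile 11 genes were called higher and 14 lower. Limited depth or the smaller difference there (median log2 ratio −0.05, against −0.15 in the second decile) may be the reason, and neither was tested.

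Same-numbered libraries deviated from their group means with a correlation of −0.34 as headed and 0.339 after the exchange, and the labels do not say that a number marks a shared animal. The replicate block gave 0 genes as headed and 4445 higher and 4662 lower after the exchange, and camera's call then changed for 2 lists, lost for histones (adjusted p = 0.112) and gained for vascular markers (0.0417). A crossed block as headed gave 0 genes higher and 0 lower.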

Other observations

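The scan of gene families by symbol and the tests of the replicate 2 headers were chosen only after the results were seen. In that scan, made with replicate 2 exchanged, 17 of 251 families with at least 10 members lay above and 40 below the other genes by camera with a preset correlation, and 0 with an estimated correlation. Of 43 collagen genes 12 were higher and 0 lower (medians of 0.22 and 0.23 in the replicates, camera adjusted p = 0.000294, and adjusted p = 0.778 with an estimated correlation). Galnt glycosyltransferases had 8 higher and 0 lower of 17 (0.27 and 0.27, adjusted p = 0.00446), cadherins with Cdh symbols 6 higher and 0 lower of 20 (0.20 and 0.24, adjusted p = 0.00446) and integrin alpha subunits 5 higher and 0 lower of 12 (0.20 and 0.29, adjusted p = 0.00446). Bmp genes had 5 higher and 0 lower of 12 (0.31 and 0.22, adjusted p = 0.00532), and protocadherins outside the clusters 6 higher and 1 lower of 12 (0.25 and 0.39, adjusted p = 0.00782). Each of these gave adjusted p = 0.778 with an estimated correlation. Related families did not all follow: integrin beta subunits (adjusted p = 0.165), claudins (0.165) and Mmp metalloproteinases (0.814) did not pass, and the clustered Pcdha genes lay below the other genes (adjusted p = 2.19e-12, and adjusted p = 0.778 with an estimated correlation).

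Among families below the other genes, translation factors with Eif symbols had 19 lower and 2 higher of 56 (medians −0.41 and −0.40, camera adjusted p = 4.94e-05), Ddx RNA helicases 13 lower and 2 higher of 33 (−0.38 and −0.43, adjusted p = 0.000667) and Prpf splicing factors 7 lower and 0 higher of 13 (−0.34 and −0.64, adjusted p = 0.000294). TBP-associated factors with Taf symbols had 8 lower and 1 higher of 22 (−0.31 and −0.40, adjusted p = 0.00306), and Mediator subunits 10 lower and 1 higher of 31 (−0.27 and −0.28, adjusted p = 0.0085). Each of these 5 families gave adjusted p = 0.778 with an estimated correlation. Ribosomal genes with Rps symbols (adjusted p = 0.059) or Rpl symbols (0.0649), elongation factors with Eef symbols (0.363), Lsm (0.211), Gtf (0.117) and mitochondrial ribosomal Mrps genes (0.251) did not pass. Mitochondrial ribosomal Mrpl genes did, with 6 lower and 1 higher of 48 (medians −0.28 and −0.41, camera adjusted p = 0.00446, and 0.778 with an estimated correlation). The ribosomal protein list fixed beforehand, which joins Rps and Rpl genes, had passed camera (adjusted p = 0.000157). No theme over several families was tested. The medians named here keep their sign with library totals, and some members overlap other intervals.

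The opposed ratios of the replicates may come from the headers of the replicate 2 columns. On 21 of 21 chromosomes both replicate 2 libraries correlated best with the other-named library of replicate 1, but this reads within chromosomes the correlations that had prompted the exchange and is no independent test of it. Had only the sign of the deposited ratio been turned, r between the libraries headed ChIP was predicted to exceed r between ChIP 1 and input 2. The median over chromosomes of the first r minus the second was −0.00757 (interquartile range 0.00684), below the predicted 0. That value goes against a turned sign alone and establishes no other explanation. The prediction was written after the same correlations had been seen over all genes, so this too is no independent test. Failed immunoprecipitation with random ratios is argued against by the rho of −0.663 between replicates, a value known when that prediction was written. The rho does not show that the immunoprecipitation worked, since a bias shared by both replicates was not tested. Exchanged headers stay open. An exchange of tubes before sequencing stays open only if the deposited ratio was also computed against the headers. That ratio was input over ChIP, as headed, at all 25056 finite intervals of replicate 2. No biological explanation was tested, since the design has 1 kind of nuclei. A satellite-rich interval, named Gm26870 (chromosome 9, 3000282 to 3038313; chosen after its values were seen), held 1.55 times the input share of reads in ChIP 1, and 0.631 times as headed or 1.58 times exchanged in replicate 2.

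The rise of the log2 ratio with gene length after the exchange is not accounted for by reads shared between intervals, since rho was still 0.113 or more in each replicate among intervals that overlap no other. Dilution of a depleted promoter was predicted to level off in long genes, but rho among the 5140 genes over 50 kb was at least 0.151. Dilution alone therefore does not account for the rise in those genes. The test did not cover shorter genes, so a part of dilution in the rise over all genes stays open. Gene density is a candidate explanation: with the number of genes within 1 Mb held fixed, rho fell to 0.0414 in replicate 1 and 0.0808 in replicate 2, from 0.136 and 0.178. A long gene itself fills part of that window, and length and density were related (rho = −0.348). The fall therefore cannot fully separate density from length. GC content, which goes with gene density and can bias ChIP libraries, was not tested, so a technical source and a biological one both stay open.

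Neighbouring genes had alike ratios after the exchange. For 3880 pairs over 50 kb apart and free of overlaps, a gene's ratio in replicate 1 and its neighbour's in replicate 2 correlated at rho = 0.35, against at most 0.0467 in size for 100 draws of random pairs. That argues against shared reads (0.35) and against noise of a single library (0.35), and with gene density regressed out rho was 0.343. Regional differences in MeCP2 binding or in base composition may underlie it as a hypothesis, and neither was tested.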
